A study of Caenorhabditis elegans with 12 samples.

How the data were processed

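Whole worms of strain KH2235 were sorted on day 6 into 2 groups of 6 libraries. Per the labels' protocols, RNA was extracted with a Qiagen miRNeasy kit and libraries were made with the Roche Kapa stranded mRNA HyperPrep kit. Per the submitters' processing notes, the tools were FastQC 0.11.8, STAR, MultiQC, Salmon 0.14.2 and DESeq2, with build WBcel235; their settings, and whether counting used strand, are not given in the sources used here.

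The deposited table holds a normalized signal, gene counts divided by 1 size factor per library, for 21982 genes and 12 libraries. In every library 100% of the values came out as whole reads within 0.001 after multiplication by the recovered factor, and the factors equalled median-of-ratios factors. For Red replicate 2 the factor lies close to 1, so its whole-number test is less decisive. Recovered totals per library ran from 30185155 to 87141961 reads. Of the genes, 479 were at 0 in all libraries. Positions and gene types came from the Ensembl release 115 annotation of the same build, in which 21896 identifiers were found. No 2 libraries of a group agreed within sampling noise.

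The main test was limma 3.58.1 in R 4.3.3 (eBayes with trend) on log2(normalized value + 1), over the 14618 genes with a mean of at least 10 normalized counts, with Benjamini-Hochberg adjusted p under 0.05. Folds are on this log2 scale and are Green against Red. The added 1 draws folds of low genes toward 0, but single values near 0 can also widen a fold beyond that of edgeR. Gene lists were tested with camera at a preset correlation of 0.01. The 38 lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the 10 highest and 10 lowest log2 folds among genes past the threshold with a mean of at least 50 and the same direction in at least 5 of 6 batches, up to 4 members of each list with the smallest p, and ret-1, sfa-1, uaf-1, uaf-2, repo-1 and rsp-1 to rsp-8 whatever their values. Exact permutation tests used all assignments of the 12 libraries to 2 groups of 6 and ignored the batches; sign flips exchanged the 2 libraries within batches.

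The labels give each batch number to 1 Green and 1 Red library, so the numbers pair the libraries. Deviations from the group means correlated within a batch by 0.11 to 0.37 (mean 0.24), against a mean of -0.05 for Green and Red libraries of different batches, across genes, which are not independent replicates. Subtracting the group means ties the second mean to the first, so it is not an independent comparison. In batches 2 to 6 each library correlated best with its own partner, but both batch 1 libraries correlated best with batch 4. A fit with the batch as a block was an alternative.

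The alternatives chosen before the data were examined were the block, pseudocounts of 0.5 and 5, no filter, a mean of at least 50, quantile normalization, median centring, robust eBayes, array quality weights, an estimated correlation for camera, and leaving out each library. Chosen after seeing the data were edgeR 4.0.16 (with TMM scaling) and DESeq2 1.42.0 on the recovered reads, leaving out batch 6, the exact permutation of list scores, and sign flips within batches. edgeR's quasi-likelihood test called 5609 genes. Of the 5719 genes called by limma, 5238 were called in the same direction by limma, limma with the block and edgeR.

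On simulated data for the gene comparison, run on 14618 genes, limma recovered 40.3% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold, with 1 false call. Only 67, 67 and 66 genes were changed by these folds, and 152 genes were called. With 5719 real calls the Benjamini-Hochberg cutoff is less strict, so these shares do not carry over to the real comparison. Permutations, enrichments and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. No genome sequence was used here, so GC content was not examined.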

Results

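RNA was sequenced from whole worms of the nematode Caenorhabditis elegans strain KH2235, which carries a splicing reporter built from a minigene of ret-1. The reporter produces GFP or mCherry depending on how its transcript is spliced. On day 6 the worms were separated by fluorescence into a Green group (mostly GFP) and a Red group (mostly mCherry). Each group had 6 libraries, and each of 6 batches held 1 Green and 1 Red library. The comparison asks how worms of the same age and strain that splice the reporter differently also differ in gene expression. Recovered totals ran from 30185155 reads in Green replicate 3 to 87141961 in Green replicate 6, and Red replicate 6 held 81537026. The labels do not say whether the libraries came from separate cultures, so p-values measure the spread between these libraries.

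Green and Red worms differed in the expression of many genes. Of 14618 genes tested, 5719 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 2781 of them higher and 2938 lower in Green. At least 2-fold differences were more often in the Red direction, with 384 genes higher and 1285 lower in Green. Among the called genes, 4822 differed in the same direction in 6 of 6 batches. The first principal component held 45.3% of the variance and separated every Green from every Red library, and the second, with 19.1%, set Red replicate 6 apart from the other 11 libraries. Without Red replicate 6, 8009 genes passed, 4287 higher and 3722 lower in Green. Centring each library on its median gene moved the median log2 fold of all tested genes from 0.04 to 0.16 and gave 4163 higher and 2337 lower calls, so small differences in either direction depend on the scaling.

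**Figure D1:**
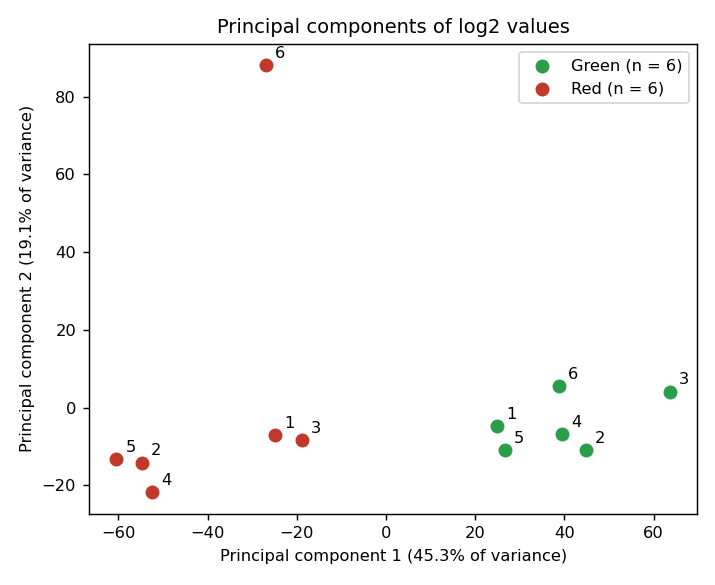
Principal components 1 and 2 of the log2 values, with each point 1 library, coloured by group and numbered by replicate. Green libraries lie at positive and Red libraries at negative values of component 1, and Red replicate 6 lies at 88.0 on component 2.

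The highest folds in Green belonged to yolk protein and collagen genes. vit-3 (X, 3567355 to 3572549, WBcel235), which encodes a yolk protein, had 25666 ± 12122 normalized counts in Green and 1717 ± 752 in Red (SD, n = 6 each), a log2 fold of 3.84 with a standard error of 0.36 (limma adjusted p = 2.67e-05). vit-4 followed with a log2 fold of 3.80. Both may share reads with vit-5, and the summed counts of vit-3, vit-4 and vit-5 had a log2 fold of 1.29. The collagen genes col-179, col-140, col-80 and col-178 had log2 folds of 3.82, 3.60, 3.32 and 3.24. T24B8.5, a secreted peptide gene used as a marker of innate immunity, rose from 78.5 ± 25.97 in Red to 679 ± 250 in Green, and the lysozyme gene lys-2 from 176 ± 50.04 to 1468 ± 726 (SD, n = 6). F57B1.9 had a log2 fold of 3.27, or 2.43 in edgeR. Its Red counts ran from 0.63 in replicate 6 to 50.8 in replicate 3, so its fold depends on the pseudocount. pgph-1 had a log2 fold of 3.01 (limma adjusted p = 0.039), with Red replicate 6 listed at 0 and a log2 fold of 1.78 without it; the call did not pass with a pseudocount of 0.5, with robust eBayes, with DESeq2 or without any 1 of Green replicates 1 to 5 or Red replicate 5.

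The 10 lowest folds in Green belonged to genes of several kinds. The cuticlin-like genes cutl-16 and cutl-9 had log2 folds of -3.19 and -3.10, and cutl-16 had 214 ± 100.02 normalized counts in Green and 1895 ± 618 in Red (SD, n = 6). ins-2, an insulin-like peptide gene, had a log2 fold of -3.25, and ces-2, a bZIP transcription factor gene, one of -2.98. The linker-histone-like gene hil-7 and the HMG-box gene hmg-6 had log2 folds of -2.75 and -2.89. Y46H3A.5 had 245 ± 67.01 in Green and 2232 ± 905 in Red (SD, n = 6, limma adjusted p = 1.08e-05). C27H5.6 and the pseudogenes C09F9.4 and K02E7.5 had log2 folds of -3.26, -3.46 and -2.98. C09F9.4 was listed at 0 in 2 Green libraries, so its fold depends on the pseudocount, and in edgeR it was -2.36. All 20 of these genes differed in the same direction in 6 of 6 batches, but the rule that chose them already required at least 5.

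**Figure D2:**
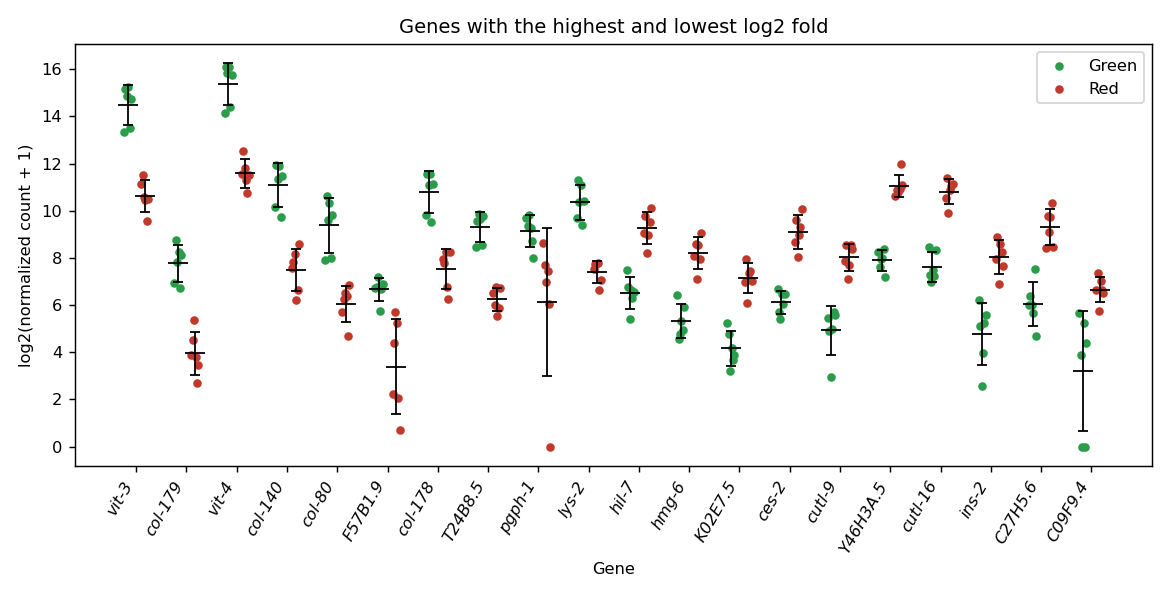
Log2(normalized count + 1) of the 10 genes with the highest and the 10 with the lowest log2 fold, each point 1 library (6 Green, 6 Red), with black marks for the mean and SD. The genes run from vit-3 at 3.84 to C09F9.4 at -3.46.

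ret-1 and the 3 splicing factors fixed beforehand differed little between the groups. ret-1 (V, 14829177 to 14847413), the gene the reporter derives from, had 35267 ± 1983 normalized counts in Green and 33751 ± 5142 in Red (SD, n = 6), a log2 fold of 0.08 with a 95% interval from -0.14 to 0.29 (limma adjusted p = 0.55, exact permutation p = 0.47). Its reads can include those of the transgene. sfa-1 (IV, 17103825 to 17110982), the branch point binding protein gene SF1, had 6900 ± 255 in Green and 8177 ± 1276 in Red, a log2 fold of -0.23 with an interval from -0.43 to -0.03. It missed the threshold in the main test (limma adjusted p = 0.051) and passed with the batch as a block (0.029), in edgeR (0.014) and by the exact permutation test (two-sided p = 0.0043, adjusted over the 4 genes 0.017), and it was lower in Green in 6 of 6 batches. That permutation ignores the batches; sign flips with the pairs kept gave p = 0.031, the smallest possible, or 0.125 adjusted over the 4 genes. uaf-1 (III, 1062794 to 1076555), the large U2AF subunit gene, had a log2 fold of -0.02 (limma adjusted p = 0.89), and repo-1 (IV, 12084478 to 12085320), a splicing factor gene, one of -0.05 (0.63).

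The other splicing factor genes named beforehand did not pass the main test. uaf-2 had a log2 fold of -0.21 (limma adjusted p = 0.20). rsp-5 had a log2 fold of 0.30 and an adjusted p of 0.062, which became 0.038 with the batch as a block. The log2 folds of rsp-1, rsp-2, rsp-3, rsp-4, rsp-6, rsp-7 and rsp-8 were -0.08, -0.08, -0.03, -0.01, 0.03, 0.13 and 0.05. Red replicate 6 was the highest Red library for ret-1 and for each of these splicing factor genes. Without it rsp-5, rsp-7 and rsp-8 passed, with log2 folds of 0.40, 0.18 and 0.25 (limma adjusted p = 0.0045, 0.034 and 0.025), and so did sfa-1.

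**Figure D3:**
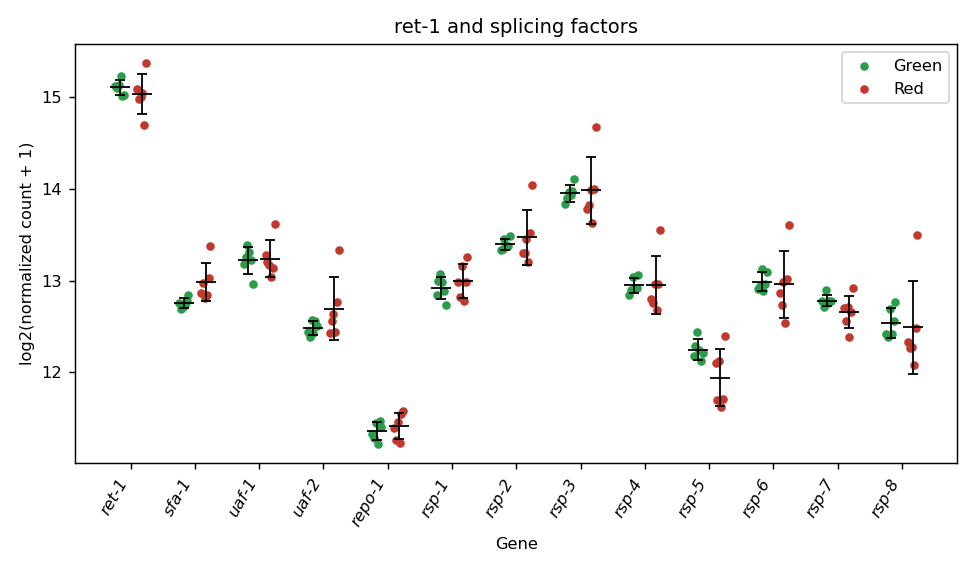
Log2(normalized count + 1) of ret-1 and 12 splicing factor genes, each point 1 library (6 Green, 6 Red), with black marks for the mean and SD. The log2 folds lie between -0.23 for sfa-1 and 0.30 for rsp-5.

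Of 38 gene lists, 26 passed camera with a preset correlation of 0.01, 20 higher and 6 lower in Green, and 0 passed with an estimated correlation. The same preset test called 26 lists for another division of the 12 libraries, which exchanged only Green replicate 5 and Red replicate 6. The counts of called member genes therefore carry the description below. They are to be read against all 14618 tested genes, of which 2781 were called higher and 2938 lower. List counts were not tested against these shares. Risen counts of cell cycle genes (9 of 39), the vacuolar ATPase (5 of 21) and longevity regulators (7 of 34) lay near the share of all genes. In the first 2 of these lists 0 genes fell, and in the third 3. An exact two-sided permutation of each list's library scores, chosen after these results were seen, passed 28 lists (19 higher, 9 lower); it tests whether a list's own level differs, not whether it differs more than other genes. That permutation ignores the batches; with the pairs kept, sign flips gave unadjusted p of 0.0625 for the proteasome and for autophagy and 0.125 for the longevity regulators among the lists it passed, against 0.031 for the others, the smallest possible. With the preset, calls that depended on single libraries were those of DAF-16 class I targets (lost without Green replicate 1 or Red replicate 3), class II targets (without Green replicate 2 or 4 or Red replicate 1, 3, 5 or 6), lipases (without Green replicate 4 or Red replicate 1, 3 or 5) and the vacuolar ATPase (without Red replicate 1 or 4). The intracellular pathogen response call was lost without Green replicate 3, 5 or 6 or Red replicate 1, 2 or 4, that of cytosolic ribosomal proteins without Red replicate 5 and that of muscle without Red replicate 3. The cytochrome P450 list passed without Green replicate 3 or Red replicate 2, 4 or 5, and the longevity regulators without Green replicate 1 or 2 or Red replicate 6.

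Most oocyte and germline genes passed as higher in Green. Of 34 oocyte and eggshell genes 30 rose and 0 fell (31 adjusted over the list alone), with a median log2 fold of 0.50, and the maternal RNA-binding protein gene spn-4 and the chitin synthase gene chs-1 had log2 folds of 0.58 and 0.59. Of 41 germline and P granule genes 31 rose and 0 fell (35 adjusted over the list alone), among them the meiotic axis gene him-3 and the Notch receptor gene glp-1, both at 0.46. Both lists had an adjusted p of 0.50 with an estimated correlation. Of 39 cell cycle and replication genes 9 rose and 0 fell (6 adjusted over the list alone), including the cyclin genes cyb-2.1 and cyb-2.2 at 0.52 each, and 18 rose without Red replicate 6; quantile normalization turned the median to -0.03, and the adjusted p was 0.64 with an estimated correlation. Of 66 sperm genes only 15 had a mean of at least 10 normalized counts, so the list does not speak for sperm genes as a class. Of these 15 genes 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.92). Those that rose were cpb-1 and spe-39, at 0.45 and 0.33. The low genes spe-4 and T22B11.1 fell, at -1.43 and -0.93.

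Yolk protein, intestine and immune lists held more risen than fallen genes. Of 6 vitellogenin genes 5 rose (5 adjusted over the list alone), vit-1 and vit-5 at log2 folds of 2.21 and 1.16. vit-3, vit-4 and vit-5 are near-identical copies, and vit-1 and vit-2 may share reads too. The authors' counting could split shared reads, so the values of these genes are uncertain. Summed, vit-1 and vit-2 had a log2 fold of 0.08, and vit-3, vit-4 and vit-5 one of 1.29. Of 29 intestine genes 13 rose, 3 fell and 13 did not pass (16 and 4 adjusted over the list alone), with the esterase gene ges-1 at 1.295 and the protease genes asp-2, cpr-1 and asp-4 at 2.14, 1.19 and 1.00. Without Red replicate 6, 17 intestine genes rose and 5 fell, and with the batch as a block 17 rose and 7 fell. Of 53 innate immune effectors 25 rose, 3 fell and 25 did not pass (26 and 3 adjusted over the list alone), the lysozyme gene lys-1 and K08D8.5 at 1.81 and 2.37. Their adjusted p with an estimated correlation was 0.50 for vitellogenins and immune effectors and 0.58 for intestine. Of 18 DAF-16 class I targets 6 rose and 2 fell (6 and 2 adjusted over the list alone; lys-7 at 1.27, dod-3 at 2.38), and of 18 class II targets 6 rose and 1 fell (6 and 1 adjusted over the list alone; clec-186 at 1.53, pes-2.1 at -0.95), each with an adjusted p of 0.50 with an estimated correlation.

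Metabolic genes rose in part. Of 26 genes of glycolysis, gluconeogenesis and the glyoxylate cycle 19 rose and 1 fell (21 and 1 adjusted over the list alone), with the phosphoenolpyruvate carboxykinase gene pck-1 at 1.18 and the pyruvate kinase gene pyk-1 at 0.58. Of 30 genes of propionate, vitamin B12 and one-carbon metabolism 18 rose and 4 fell (18 and 5 adjusted over the list alone), with acdh-1 of the propionate shunt at 1.99 and cbs-2 at -1.74. Of 22 genes of fatty acid synthesis and desaturation 8 rose and 1 fell (8 and 1 adjusted over the list alone), the desaturase gene fat-7 at 1.83 and the fatty acid synthase gene fasn-1 at -0.62. Of 35 lipase and beta-oxidation genes 12 rose and 3 fell (12 and 3 adjusted over the list alone; acox-1.4 at 2.26; median -0.01 under quantile normalization), and of 28 oxidative stress and glutathione genes 9 rose and 1 fell (9 and 1 adjusted over the list alone; gst-10 at 1.90, dhs-8 at -2.16). All 5 lists had an adjusted p of 0.50 with an estimated correlation. Without Red replicate 6, 14 fatty acid synthesis genes and 17 oxidative stress genes rose. Of 120 cytochrome P450 and UDP-glucuronosyltransferase genes 36 rose and 18 fell (36 and 18 adjusted over the list alone; cyp-35B1 at 1.55), camera adjusted p = 0.068; its median of 0.10 was slightly below 0 with TMM scaling. Without Red replicate 6, 36 rose and 32 fell, with a median of -0.04.

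Proteasome and mitochondrial ribosomal protein genes rose in part. Of 33 proteasome genes 16 rose and 0 fell (19 adjusted over the list alone; rpn-7 at 0.32), of 67 mitochondrial ribosomal protein genes 18 rose and 0 fell (14 adjusted over the list alone; mrps-34 at 0.45), and of 13 mitochondrial unfolded protein response genes 5 rose (5 adjusted over the list alone; the chaperonin gene hsp-60 at 0.57), each with an adjusted p of 0.50 with an estimated correlation. Without Red replicate 6 the risen genes were 31, 36 and 8. Of 80 cytosolic ribosomal protein genes 2 rose and 2 fell (0 and 1 adjusted over the list alone), but 65 rose without Red replicate 6; the respiratory chain list had 5 of 42 risen (0 adjusted over the list alone) and 29 without that library. The vacuolar ATPase list had 5 of 21 risen (4 adjusted over the list alone; vha-7 at 0.46) and 12 without Red replicate 6. With quantile normalization the medians of the ribosomal, respiratory chain and vacuolar ATPase lists were -0.01, -0.02 and -0.04, and with an estimated correlation their adjusted p was 0.69, 0.69 and 0.50. None of the 12 mitochondrially encoded genes passed (0 adjusted over the list alone), and nduo-6 and ndfl-4 had adjusted p of 0.062 and 0.097, or 0.0062 and 0.019 with the batch as a block. Of 26 body-wall muscle genes 11 rose and 2 fell (12 and 2 adjusted over the list alone), unc-27 and tnt-2 of troponin at 1.59 each and the myogenic factor gene hlh-1 at -1.33 (adjusted p = 0.58 with an estimated correlation).

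Moulting, neuropeptide, neuronal, pharynx and histone lists held more fallen than risen genes. Of 24 moulting and larval cuticle genes 14 fell and 1 rose (15 and 2 adjusted over the list alone), with a median log2 fold of -1.12; the fibrillin-like gene fbn-1 had 601 ± 205 normalized counts in Green and 3134 ± 1091 in Red (SD, n = 6), and wrt-10, noah-1 and the nuclear receptor gene nhr-25 had log2 folds of -2.24, -1.95 and -1.72. Of 127 neuropeptide genes 58 fell, 3 rose and 66 did not pass (61 and 3 adjusted over the list alone), nlp-67 and ins-4 at -1.69 and -1.43. Without Red replicate 6, 65 neuropeptide genes fell and 7 rose. Of 30 neuronal function genes 11 fell, 1 rose and 18 did not pass (11 and 1 adjusted over the list alone), the POU factor gene unc-86 at -1.93 and the tyrosine decarboxylase gene tdc-1 at 0.57. Of 20 pharynx genes 7 fell and 1 rose (11 and 1 adjusted over the list alone), pha-4 at -0.85 and lys-8 at 1.65. Of 53 histone genes 27 fell and 0 rose (29 adjusted over the list alone), the linker histone gene his-24 at -1.91; histone genes share near-identical sequences, and the list's score was higher in Red replicate 6 than in the other Red libraries by 1.15. These 5 lists had an adjusted p of 0.50 with an estimated correlation. Of 24 embryonic patterning genes 9 fell and 5 rose (11 and 7 adjusted over the list alone), the homeobox gene ceh-43 at -2.19 (camera adjusted p = 0.18), and 11 fell and 8 rose without Red replicate 6.

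**Figure D4:**
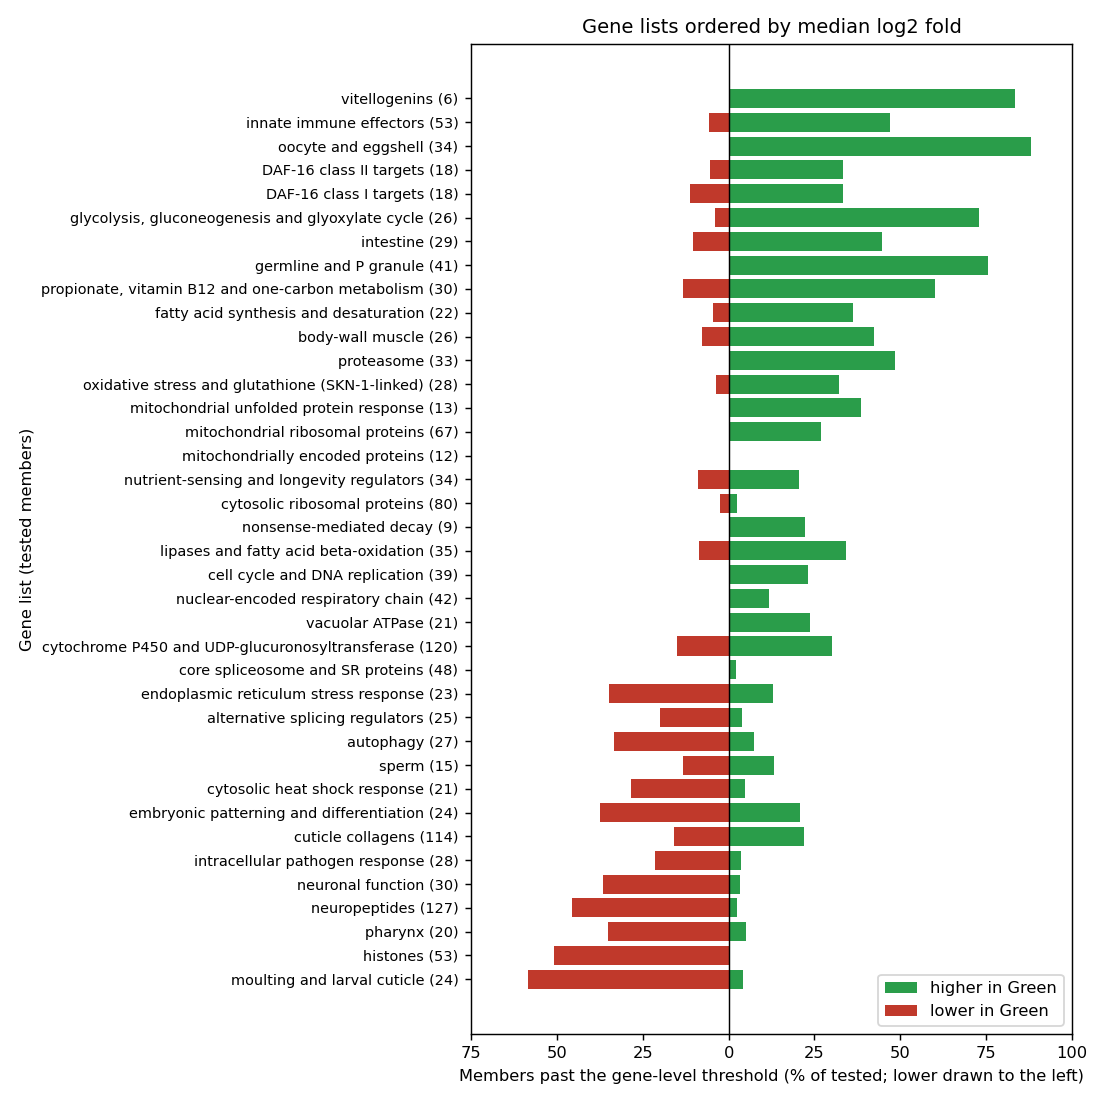
Share of each list's tested members past the gene-level threshold, higher in Green to the right and lower in Green to the left, ordered by median log2 fold, with tested members in brackets. Of the 34 oocyte and eggshell genes 30 rose, and of the 127 neuropeptide genes 58 fell.

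Other lists held calls in both directions or few calls. Of 48 core spliceosome and SR protein genes only M28.5 passed, at 0.31 (limma adjusted p = 0.043; 0 genes adjusted over the list alone), a call lost when any of 9 single libraries was left out; under quantile normalization the list's median was -0.15 and 19 members fell. Without Red replicate 6, 6 members rose and 1 fell, with a median of 0.06 (camera adjusted p = 0.050). Of 25 alternative splicing regulators 5 fell and 1 rose (5 and 1 adjusted over the list alone), with unc-75, mec-8, sup-12 and exc-7 at -1.58, -0.53, -0.71 and -0.40 (camera adjusted p = 0.32); the median of -0.04 was 0.09 after centring. Without Red replicate 6, 6 rose and 6 fell and the median was 0.05. The list's mean score was lower in Green in 6 of 6 batches, but in batch 4 the libraries were almost equal (-0.0496 in Green, -0.0493 in Red). In batch 6 the scores were -0.042 in Green and 0.39 in Red. An exact permutation that ignores the batches gave an adjusted p of 0.013. Sign flips within batches gave an unadjusted p of 0.031, the smallest possible. Of 27 autophagy genes 9 fell and 2 rose (10 and 3 adjusted over the list alone), with epg-2, sqst-1 and lgg-1 at -1.34, -0.71 and -0.44 (camera adjusted p = 0.12), and 12 fell and 5 rose without Red replicate 6. Of 28 intracellular pathogen response genes 6 fell and 1 rose (4 and 1 adjusted over the list alone; pals-3 at -1.43), with an adjusted p of 0.69 with an estimated correlation. Of 21 heat shock genes 6 fell and 1 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.22), led by the near-identical copies F44E5.4 and F44E5.5 at -1.57 and -1.53; without Red replicate 6, 8 fell and 6 rose. Of 23 endoplasmic reticulum stress genes 8 fell and 3 rose (8 and 4 adjusted over the list alone; pdi-6 at -0.54, ero-1 at 0.38; camera adjusted p = 0.35), and without Red replicate 6, 8 fell, 5 rose and the median turned from -0.02 to 0.01. The medians of the autophagy, heat shock, endoplasmic reticulum stress and sperm lists were above 0 after centring. Of 9 nonsense-mediated decay genes 2 rose (1 adjusted over the list alone; smg-5 at 0.32; camera adjusted p = 0.12), with a quantile-normalized median of -0.01; 4 rose without Red replicate 6. Of 34 nutrient-sensing and longevity regulators 7 rose and 3 fell (5 and 3 adjusted over the list alone), daf-18 and age-1 at 0.52 and 0.40 and hlh-30 at -0.38 (camera adjusted p = 0.058), and 13 rose without Red replicate 6 (0.041).

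The number of called members in many lists depended on the scaling. With quantile normalization and with centring, in that order, the risen genes were 4 and 23 for the proteasome, 8 and 38 for mitochondrial ribosomal proteins, 0 and 10 for cytosolic ribosomal proteins, 1 and 10 for the respiratory chain and 2 and 10 for the vacuolar ATPase. They were 3 and 8 for the mitochondrial unfolded protein response, 4 and 12 for fatty acid synthesis, 8 and 15 for oxidative stress, 3 and 15 for longevity regulators, 4 and 14 for the cell cycle, and 0 and 3 for mitochondrially encoded genes. The fallen genes, in the same order, were 25 and 40 for neuropeptides, 15 and 21 for histones, 3 and 5 for pharynx, 9 and 5 for alternative splicing regulators, 11 and 5 for autophagy, 7 and 2 for heat shock, 12 and 3 for endoplasmic reticulum stress, and 11 and 17 for the cytochrome P450 list. In the other direction, 6 and 7 neuropeptide genes, 4 and 8 embryonic patterning genes, 0 and 5 alternative splicing regulators and 0 and 5 autophagy genes rose, and 6 cell cycle and 3 vacuolar ATPase genes fell with quantile normalization alone. The counts moved less in the oocyte list, with 28 and 31 risen, and in the moulting list, with 13 and 14 fallen.

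Cuticle collagens went both ways. Of 114 collagen genes 25 rose and 18 fell (25 and 20 adjusted over the list alone), with a median log2 fold of -0.22 but a mean of 0.04, and camera gave an adjusted p of 0.92. The median was 0.19 under quantile normalization. col-119 had 3662 ± 1486 normalized counts in Green and 502 ± 252 in Red (SD, n = 6).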

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

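The tests of the yolk genes, the germline share, exchanged labels, the scaling factor and the collagen scores were chosen after the results were seen. The zygotic gene list and the depth test of Red replicate 6 were written before their values were seen, but after related lists had been.

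The moulting, neuronal function and embryonic patterning lists held more genes lower than higher in Green (14 and 1, 11 and 1, 9 and 5), but many of their genes did not pass, embryonic patterning did not pass camera (adjusted p = 0.18), and none of the 3 passed with an estimated correlation. A list of 51 zygotic and late embryonic genes outside the first 38 lists had a median log2 fold of -0.84, with 32 genes lower, 2 higher in Green and 17 not passing (exact permutation p = 0.0022, the smallest possible), which is consistent with more embryos or larvae inside Red worms; many of these genes are also expressed in adult tissues, and its most abundant members sax-7 and hmr-1 did not pass (log2 folds of 0.16 and 0.09). As the whole cause of the higher neuronal and embryonic transcripts in Red, a lower share of germline RNA would raise all somatic markers alike. The intestine score minus the neuronal score was instead higher in Green by 0.77 (exact permutation p = 0.0022). This does not exclude a lower germline share as a part, since 30 of 34 oocyte and 31 of 41 germline genes were higher in Green. Dilution by progeny as the whole cause of the yolk protein difference would move all vitellogenins alike. Since near-identical copies share reads, their counts were summed, and the log2 folds were 1.29 for vit-3, vit-4 and vit-5, 0.65 for vit-6 and 0.08 for vit-1 and vit-2. Highest and lowest differed by 1.213 (standard error 0.18, exact permutation p of the range 0.0022). Progeny, a difference in adult expression of the same genes and a slower development of the sorted worms remain open and were not separated. The same holds for a lower germline share as a part of the cause.

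Red replicate 6 stood apart from the other Red libraries, with a root mean square log2 distance of 0.85 against 0.40 to 0.47 for the others. On the axis from the Red mean (0) to the Green mean (1) of batches 1 to 5 it lay at 0.30 and Green replicate 6 at 0.94, which argues against exchanged labels. Thinned to 30185155 reads, its distance was 1.02 times the full-depth one, so depth does not account for it. A wrong scaling factor would move all genes alike, but its ribosomal score exceeded and its cytochrome P450 score fell below the other Red libraries, a gap of 1.502. No biological explanation was tested, since the labels give this library no condition of its own.

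The cuticle collagen level varied between batches. Over the 6 batches the Green and Red collagen scores correlated with Pearson's r = 0.97 (exact permutation p = 0.0056) and Spearman's rho = 0.89 (exact permutation p = 0.033), and r was 0.97 without the 2 batches farthest from the median; among the 38 lists so compared the adjusted p of r was 0.21, so it did not pass, and by rho the intestine (1) and DAF-16 class II (0.94) lists stood higher. A condition shared by the 2 libraries of a batch may account for it. Sequencing depth could be neither shown nor excluded, since the score correlated with total reads over 12 libraries with r = 0.33 (permutation p = 0.30) and rho = 0.27 (permutation p = 0.40), and r was 0.19 without 2 libraries.

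Of 276 groups of 6 values examined, 27 held a library far from the other 5, where chance gives about 1 in 20 groups (13.8), and 16 of the 27 were Red replicate 6. In that library the normalized counts were 909 for his-32, 4798 for rpl-24.2, 16812 for rsp-2, 26191 for rsp-3, 12022 for rsp-4, 12493 for rsp-6, 11521 for rsp-8, 10611 for sfa-1, 12583 for uaf-1 and 10350 for uaf-2. Its mean log2 deviation was 0.39 for alternative splicing regulators, -0.73 for the cytochrome P450 list, 0.19 for endoplasmic reticulum stress, 1.37 for histones and 0.34 for the respiratory chain, and its total was 81537026 reads. Green replicate 3 was apart with 16165 normalized counts for M28.5, 18703 for cyb-2.2, 6268 for him-3, 6519 for pdi-6 and 11659 for rpn-8, and a cell cycle score of 0.21. Green replicate 5 had 183 for C27H5.6, a muscle score of -0.15 and a cytosolic ribosomal score of -0.092. Red replicate 5 had 4030 for Y46H3A.5, and Green replicate 1 had 97.5 for dhs-8.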

How the results depend on the processing

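edgeR with its TMM scaling, DESeq2, leaving out batch 6, the permutation of list scores and sign flips within batches were chosen after seeing the data. The other alternatives were chosen before the data were examined. None of the 5719 called genes changed sign in any alternative, but fewer stayed called. The lowest number still called in the same direction was 3716, under quantile normalization, where 4708 genes passed. Leaving out 1 library gave 4451 to 8009 genes, the highest without Red replicate 6, and from 1977 (without Green replicate 3) to 4287 (without Red replicate 6) genes higher in Green; array quality weights gave 9048 genes, 4915 of them higher. Median centring gave 64.05% of calls higher in Green against 48.6% as reported, and a mean of at least 50 gave 57.04%. With the batch as a replicate block 6701 genes passed, 5661 of them among the reported ones, and 26 lists.

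Among ret-1, sfa-1, uaf-1 and repo-1, 0 passed as reported; sfa-1 passed, making 1, with the replicate block, a mean of at least 50, array quality weights, edgeR with and without the block, DESeq2 and leaving out batch 6, and 2 (sfa-1 and repo-1) with quantile normalization. Leaving out 1 library gave 0 or 1, the latter without Red replicate 1, 3, 4 or 6. Fewer tested genes ease the adjustment with the higher minimum; otherwise the cause was not tested. The block changed the calls of sfa-1, rsp-5, nduo-6 and ndfl-4 and no other call of a gene or list named in the text.

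The number of lists fell from 26 to 17 with a mean of at least 50 and to 0 with an estimated correlation, which widens the null by the correlation between members; it was 28 by exact permutation and 22 to 26 with 1 library left out. Under quantile normalization the median changed sign in 9 lists, to -0.15 for the core spliceosome (camera adjusted p = 2.41e-05), -0.013 for cytosolic ribosomal proteins, -0.019 for the respiratory chain, -0.040 for the vacuolar ATPase -0.030 for cell cycle genes, -0.0095 for nonsense-mediated decay, -0.0071 for lipases, 0.19 for collagens and 0.17 for sperm; the cause was not tested. The smallest library held 30185155 reads, and in simulated data for the gene comparison most 1.5-fold changes were missed. Far fewer genes were changed there than were called here, so that share does not carry over to the real comparison.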

Other observations

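The tests of gene families, the X chromosome, intron number, other splits and sign flips within batches were chosen after the results were seen.

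Several gene families differed together, where a family is a set of genes whose names share the letters before the number. Shared letters do not show that genes are related in sequence, and the enriched families include unc, osm and him. Of 126 families with at least 10 tested members, 13 were enriched among genes lower in Green and 5 among genes higher (hypergeometric test, Benjamini-Hochberg, genes not being independent). The 13 include his, flp, ins and nlp, which the histone and neuropeptide lists cover, and some asp, spp and clec genes also belong to the intestine, immune or DAF-16 lists. Of 100 fbxb genes, which encode F-box proteins, 87 were lower in Green and 0 higher, with a median log2 fold of -1.32; fbxb-10 had 91.6 ± 24.5 normalized counts in Green and 286 ± 46.99 in Red (SD, n = 6). Of 39 fbxc genes 24 were lower and 3 higher, of 20 skr genes (Skp1-related ubiquitin ligase components) 11 and 3, of 27 sdz genes 18 and 1, of 23 cutl genes 16 and 1, and of 20 gcy receptor guanylyl cyclase genes 13 and 0, the last with 7 lower under quantile normalization. Higher in Green were 9 of 11 asp aspartyl protease genes, 11 of 17 spp saposin-like genes and 37 of 108 clec lectin genes, though 15 clec genes were lower and the clec family's mean score did not separate the groups (exact permutation p = 0.10, against 0.0022 for asp and for spp), although it was higher in Green in 6 of 6 batches (exact sign flip permutation p = 0.031). The medians of the 18 enriched families kept their direction under quantile normalization, centring and TMM scaling. Members of some of these families resemble each other, and how the authors' counting split shared reads is not given in the sources used here. Single members are therefore uncertain.

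Genes on the X chromosome were lower in Green more often than autosomal genes. Of 2101 X-linked genes 33.1% were lower and 11.9% higher, against 17.9% and 20.3% of 12486 autosomal genes. The imbalance of 695 lower to 250 higher X-linked genes was smaller with quantile normalization (534 and 336) and centring (529 and 360). The X mean minus the autosomal mean was lower in Green than in Red in 6 of 6 batches (exact permutation p = 0.0043). Of 573 pseudogenes 197 were lower and 34 higher, or 124 and 72 with quantile normalization, where the median moved from -0.28 to -0.02, and 167 and 62 after centring. Red libraries had more genes above 0, with 19376 ± 676 against 18262 ± 584 in Green (SD, n = 6, exact permutation p = 0.011), and with every library thinned to 30185155 reads the means were 18957 and 17809 (exact permutation p = 0.013). With the pairs kept the differences did not pass (exact permutation within batches, p = 0.094 and, thinned, 0.0625), as batch 6 went the other way with 18281 genes in Red and 18879 in Green, or 17617 and 17883 when thinned.

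A hypothesis that differing splicing activity shifts intron-rich genes as a class was not borne out. Across 14021 protein-coding genes, which are not independent, Spearman's rho of intron number with the log2 fold was 0.019. A rank correlation does not describe the 270 genes without introns, whose median log2 fold was -0.40 against 0.02 to 0.08 for the classes with introns; that break was not tested further.

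Of 100 splits of the 12 libraries, drawn from 462, only 1, the real one, gave 5719 genes, and the highest other gave 3242. That other split differs from the real one by the exchange of Green replicate 5 and Red replicate 6, and 97 of the other splits gave 0 genes. The share with as many genes was thus 1 in 100, or 1 in 32 among the splits that part every batch. Such shares make chance unlikely for the gene count but cannot exclude it. For the lists 2 of 100 splits, the real one included, gave 26, with a median of 17 over the other splits. Many of these splits keep most libraries in their real groups, so part of the 17 can come from the real difference. Random splits exchanging 6 libraries, which mix the groups evenly, still called from 7 to 22 lists. A preset correlation that calls so many there is too small for these libraries, so the number of lists is not evidence by itself. Among the 32 splits that part every batch, the highest other called 3 genes without and 1642 with the block, the latter exchanging both libraries of batch 6, and that split also gave 26 lists with the block. The list count is not taken to exclude chance. Of the 100 splits, 32, the real one included, called 20 or more lists. Without the block the highest other of the 32 splits that part every batch gave 25. With the block 2 of these 32, the real one included, gave 26.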
